A study of Mus musculus with 2 samples.

How the data were processed

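Spleen cells of naive Il7r-cre; Rosa26-lsl-tdTomato mice, enriched for CD11c and sorted by tdTomato, had been profiled with the droplet method of 10x Genomics (3′ kit) and sequenced on an MGI instrument, 1 library from tdTomato-positive cells (L-cDC) and 1 from tdTomato-negative cells (M-cDC). The deposited matrices hold raw UMI counts per gene and cell barcode, written by Cell Ranger 6.1.2 per the file headers, against GRCm38 (mm10) per the labels. The deposited files of other content hold the gene names with Ensembl identifiers and the barcodes that the authors' run had called as cells; both libraries list the same 31053 genes. Coordinates came from an annotation of GRCm38 by Ensembl identifier, and 446 of 446 identifiers looked up were found.

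Barcodes with fewer than 500 genes or more than 10% mitochondrial UMIs were removed, which left 4086 of 4939 in L-cDC and 5848 of 6674 in M-cDC. Doublets were scored per library with Scrublet at an expected rate of 0.08. Its automatic thresholds were 0.547 for L-cDC, which marked 14 cells, and 0.258 for M-cDC, which marked 248, so the lower was applied to both and removed 143 and 248 cells; this choice was made after seeing the thresholds. The kept cells were normalised to 10000 UMIs, log-transformed and clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours with Leiden at resolution 1.0 and seed 1. Immunoglobulin, T cell receptor, hemoglobin, mitochondrial, ribosomal protein and sex-linked genes were left out of the variable genes. A cluster was named after the fixed marker list with the highest scaled score if the score was at least 0.3, at least 3 markers were detected at 10 CPM and at least 1 was among its top 10 genes, with no more markers of another list there. Cluster 8 was kept apart because at least 2 markers each of cDC2 and pDC were among them. The thresholds of this rule were not part of the design written beforehand, and the rule was revised after a first naming had been seen. The first version did not require a marker among the top 10 genes and let lists with few detected markers lead, which named cluster 6 cDC2-like, cluster 7 mature Ccr7+ DC-like and cluster 8 pDC-like and left clusters 1 and 17 unnamed. Results with cluster 6 or 8 counted as cDC2-like and with cluster 7 counted as mature are given among the alternatives. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

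For each class, UMIs were summed per library and scaled to the sum of the class and library (CPM) with exact Poisson 95% intervals, and the ratio of L-cDC over M-cDC was given with an exact conditional binomial 95% interval. Genes were considered with at least 20 CPM in the higher library and at least 50 UMIs over both, a library at 0 counts was set to a floor of 3 counts over the class, and a count of genes at 1.5-fold describes these 2 libraries by a fixed size. Shares of cells have exact Clopper-Pearson 95% intervals. With 1 library per group no statistical test between the groups was made, no p-value is given and cells were not treated as replicates. For each fixed gene list with at least 5 considered members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description, and a median outside their central 95% is called outside the random range. The comparisons, gene lists, cell filters and the rule for named genes had been written down before the files were opened, except for the lists of ribosomal protein and mitochondrial genes. Their medians were 0.12 and 0.017 in cDC1-like cells and -0.049 and 0.10 in cDC2-like cells.

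By that rule the text names, for each of the cDC1-like and cDC2-like comparisons, the 12 considered genes with the highest and the 12 with the lowest ratio whose interval leaves out 1, other than unnamed gene models and the gene families left out of clustering. It also names up to 4 members with the largest absolute ratio of each list and a fixed set of lineage genes, among them Xcr1, Clec9a, Cd8a, Irf8, Sirpa, Clec4a4, Cd4, Irf4, Zbtb46, Flt3 and Il7r. Some genes that the rule covers are not reported here. Genes named outside the rule are described as chosen after their values were seen, and the leading genes of clusters are those of highest fold over the other clusters. The calculation was checked on simulated data of the same depths, in which 95.3% and 94.9% of intervals held the true ratio in cDC1-like and cDC2-like cells, and 65 of 66 and 64 of 66 genes changed by 2-fold passed 1.5-fold. The simulated counts followed the Poisson distribution that the intervals assume. They lacked the gathering of UMIs in single cells seen in the data. The check therefore cannot show that the intervals or error rates hold for the real libraries. Alternatives varied the cell filters, doublet removal, clustering resolution, joint clustering, class assignment and membership, the denominator of shares, scaling, the expression minimum, a pseudocount, cell depth and the cell with most UMIs of each gene. tdTomato status could not be checked, since the reporter is not among the genes listed.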

Results

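The series measured gene expression in single dendritic cells from the spleens of naive Il7r-cre; Rosa26-lsl-tdTomato mice aged 7 to 9 weeks. These mice are designed so that a cell turns on the red protein tdTomato for good once it, or an ancestor, has expressed Il7r. Il7r is the interleukin 7 receptor chain of lymphoid progenitors. Cells bearing CD11c, an integrin of dendritic cells, were enriched with magnetic beads and sorted into tdTomato-positive cells (L-cDC, taken as the cells with an Il7r history) and tdTomato-negative cells (M-cDC). Il7r transcripts were also found in M-cDC cells. The sort was on tdTomato and not on Il7r transcripts, so these do not show how cleanly it separated cells by Il7r history. Each group had 1 library, so no difference between the groups could be checked against replicates, and intervals cover counting error only. The deposited L-cDC library held 4939 cell barcodes with 40170515 UMIs (unique molecular identifiers, counted transcripts) and a median of 7652 UMIs per barcode. The M-cDC library held 6674 barcodes with 52973960 UMIs and a median of 7156. After the removal of sparse, damaged and doublet-like barcodes, 3943 L-cDC cells with a median of 8573 UMIs and 5600 M-cDC cells with a median of 7664 UMIs were compared. The stated question of the series was how type 1 and type 2 conventional dendritic cells (cDC1, which specialise in presenting antigen to CD8 T cells, and cDC2, which mainly prime CD4 T cells) of each origin compare in gene expression.

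Both libraries held the same main classes of dendritic cell in different proportions. Cells with cDC1 markers such as Xcr1 and Clec9a made up 5.53% (4.84 to 6.29) of L-cDC cells and 13.02% (12.1 to 13.9) of M-cDC cells, with exact Clopper-Pearson 95% intervals in parentheses. Cells with cDC2 markers such as Sirpa and Clec4a4 made up 3.98% (3.39 to 4.64) of L-cDC cells and 17.3% (16.3 to 18.3) of M-cDC cells. A class scored highest by markers of mature, migrating dendritic cells such as Ccr7 and Fscn1 was the largest in both, at 50.6% (49.0 to 52.2) and 49.9% (48.6 to 51.2). Cluster 8, which carried markers of cDC2 (Cd209a, Cd209d) together with markers of plasmacytoid dendritic cells (pDC; Siglech, Tcf4, Lag3), made up 4.92% (4.27 to 5.64) of L-cDC and 2.46% (2.07 to 2.90) of M-cDC. Dividing cells made up 1.90% (1.499 to 2.38) and 4.95% (4.39 to 5.55). A further 26.7% of L-cDC and 11.9% of M-cDC cells fell in 8 clusters left unnamed. None of the markers of the highest-scoring list was among the top 10 genes of any of these clusters. Clusters 7, 9, 12 and 15 among them scored highest for the mature markers. They held 9.003%, 4.49%, 4.64% and 2.31% of L-cDC and 0.0179%, 2.05%, 1.54% and 0.839% of M-cDC cells. The near-equal shares of the mature class therefore depend on the naming rule. Cluster 6, also unnamed, scored highest for the cDC2 markers and held 4.51% of L-cDC and 6.43% of M-cDC cells. With it counted as cDC2-like, that class made up 8.50% of L-cDC and 23.75% of M-cDC cells. The cDC2-like class joined cluster 4 (led by Ffar2 and Ltb, 94 L-cDC and 758 M-cDC cells) and cluster 11 (led by Mgl2, Lyz2 and Cd209a, 63 and 212 cells). These shares describe cells that had passed a CD11c bead enrichment and a tdTomato sort, not the spleen, and whether the isolation itself raised maturation genes was not tested. L-cDC cells were deeper (median 15843 UMIs against 13934 in cDC1-like and 9157 against 7253 in cDC2-like cells). Counted among cDC1-like plus cDC2-like cells alone, cDC1-like cells were the larger part of L-cDC, at 58.1% against 42.9% in M-cDC, and when every cell was forced into 1 of the 2 classes by its marker means, cDC2-like cells made up 88.2% of L-cDC and 79.5% of M-cDC.

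**Figure D1:**
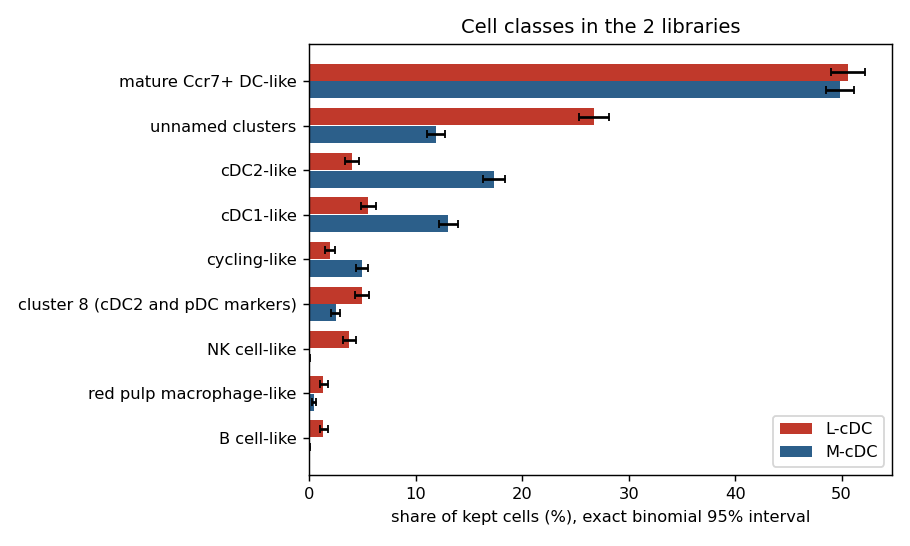
Share of kept cells (percent, horizontal axis) in each cell class (vertical axis) for the L-cDC library (red) and the M-cDC library (blue), with exact binomial 95% intervals as error bars. The cDC1-like and cDC2-like bars are shorter in L-cDC, the bars of cluster 8 and of the unnamed clusters are longer in L-cDC, and the mature Ccr7+ bars are near 50.6% and 49.9%.

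The cDC1-like cells of both origins had nearly the same expression profile, with a correlation of 0.991 across genes. The genes that define cDC1 lay close together: Xcr1, the receptor for the chemokine XCL1, was at 527 CPM in L-cDC and 576 CPM in M-cDC (CPM, UMIs scaled to the sum of that class and library); Clec9a, which senses dead cells, was at 212 and 228 CPM; Irf8, the transcription factor cDC1 depend on, was at 1742 and 1894 CPM; and Cd8a was at 214 and 205 CPM. Flt3, the growth factor receptor of dendritic cells, was at 151 and 166 CPM and Zbtb46, a transcription factor of conventional dendritic cells, at 46.6 and 48.7 CPM. Of 4692 genes with enough counts, 43 differed by 1.5-fold or more, 20 higher in L-cDC and 23 lower. With CPM taken without mitochondrial, ribosomal protein and immunoglobulin genes, 82 did, 51 higher and 31 lower. The count and its balance also changed when cells were classed by marker means (114 genes, 96 higher and 18 lower). With each library clustered alone, 113 genes differed, 73 higher and 40 lower. The balance tilted further to lower genes with each cell thinned to a fixed number of UMIs (523 genes, 125 higher and 398 lower). It did so too at a minimum of 5 CPM (405 genes, 153 higher and 252 lower). M-cDC had the deeper sum, so at low counts the minimum of 50 UMIs over both admits genes lower in L-cDC more readily. These 2 tilts are therefore partly built into the filter. At a minimum of 50 CPM, 11 genes differed, 9 higher and 2 lower.

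Among the genes higher in the cDC1-like cells of L-cDC, Fabp5, a fatty acid binding protein, was at 40.2 CPM (33.8 to 47.5) against 17.7 CPM (15.2 to 20.5), a ratio of 2.27-fold (95% interval 1.81 to 2.85). Cpne8 was higher by 2.30-fold (95% interval 1.70 to 3.10). Gadd45b, a stress-response gene, was 1.73-fold higher and Fscn1, the actin-bundling fascin of mature dendritic cells, 1.52-fold (95% interval 1.15 to 1.99) higher. The replication histone gene Hist1h2ap was 1.85-fold higher, Rpgrip1 1.83-fold, Fam98b 1.55-fold and Tcof1 1.54-fold. Gzma, the granzyme of cytotoxic lymphocytes, was at 29.2 CPM and 0 in M-cDC, at least 97.9-fold higher against a floor of 3 counts (exact lower 95% limit 78.2-fold), but 97.0% of its 101 UMIs came from 1 cell. The chemokine gene Ccl5 (144 and 83.8 CPM) and the early-response gene Egr3 (1.52-fold) also drew 31.9% and 37.9% of their L-cDC UMIs from 1 cell each. The direction of some of these genes depended on doublet removal: with doublet-like cells kept, Fabp5, Gadd45b, Fscn1 and Ccl5 were lower in L-cDC, at log2 ratios of -0.36, -0.49, -1.12 and -0.31.

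Among the genes lower in the cDC1-like cells of L-cDC, Cdkn1a, the cell-cycle inhibitor p21, was at 14.2 CPM in L-cDC and 30.6 CPM in M-cDC, 2.16-fold (95% interval 1.59 to 2.98) lower. Gt(ROSA)26Sor, the transcript of the Rosa26 locus into which the tdTomato cassette was placed, was at 19.96 CPM in L-cDC and 33.4 CPM in M-cDC, 1.67-fold (95% interval 1.29 to 2.20) lower. A pair of interferon-induced membrane genes were lower together, Ifitm3 at 92.6 and 148 CPM (1.59-fold lower) and Ifitm2 at 17.9 and 28.5 CPM (1.59-fold lower). Lgals3, the lectin galectin 3, was at 245 CPM in L-cDC and 372 CPM in M-cDC. The replication genes Orc6 (1.78-fold lower) and Hist1h1b (1.63-fold) were lower too, as were Morc2a (1.71-fold), Ggps1 (1.69-fold), Tmem199 (1.63-fold), Fam53a (1.62-fold), Rrs1 (1.58-fold) and Znhit6 (1.56-fold). Orc6 (0.58) and Hist1h1b (0.14) turned higher by log2 ratio when each library was clustered alone, and Cdkn1a (0.047) when cells were classed by marker means.

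By gene group, 5 of 20 fixed lists lay outside the random range in the cDC1-like cells, with few members past 1.5-fold. The number rose to 9 with doublet-like cells kept, 10 with each library clustered alone and 12 of 24 when cells were classed by marker means, and fell to 3 at no more than 5% mitochondrial UMIs and 1 with cells thinned to 3000 UMIs. The 27 measured cDC1 markers had a median log2 ratio (L-cDC over M-cDC) of -0.10, at percentile 23.2 of 10000 random lists matched on size and expression and so inside their central 95%, and none of them differed by 1.5-fold. Markers of mature Ccr7+ dendritic cells were slightly higher in L-cDC, with a median of 0.14 (percentile 99.8) over 8 members, of which 1, Fscn1, passed 1.5-fold. Oxidative phosphorylation genes, which encode the respiratory chain, had a median of 0.084 (percentile 100) with 36 of 36 members inside 1.5-fold, and ribosomal protein genes, a list not fixed beforehand, stood at 0.12 (percentile 100). Genes of ESAM-low cDC2, a splenic cDC2 type that shares genes with monocytes, were lower in L-cDC at -0.30 (percentile 0.03), with 1 of 5, Lgals3, past 1.5-fold. Myeloid program genes stood at -0.21 (percentile 1.45) and MHC class I and cross-presentation genes at -0.14 (percentile 0.7), each with no member past 1.5-fold. Interferon-stimulated genes (-0.031) and MHC class II genes (-0.068) lay inside the random range. In simulated libraries of the same depth, 0.0893% of the 4478 genes left unchanged passed 1.5-fold by counting error. The mature-marker median was -0.46 when doublet-like cells were kept and the MHC class I median 0.0078 when cells were classed by marker means.

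More genes differed between the cDC2-like cells of the origins, and those of L-cDC carried more transcripts of lymphoid, pDC and maturation genes. Il7r itself (Ensembl identifier ENSMUSG00000003882, chromosome 15, 9505788 to 9530176 in GRCm38) was at 32.7 CPM (24.3 to 43.0) in L-cDC and 14.7 CPM (12.02 to 17.7) in M-cDC, 2.23-fold (95% interval 1.57 to 3.14) higher. The cells were sorted by a reporter that Il7r expression turns on. Higher Il7r in L-cDC, here and in the groups of cells below, is therefore not independent of the sort. Tcf4, the transcription factor that directs pDC development, was at 187 CPM in L-cDC and 103 CPM in M-cDC, 1.82-fold (95% interval 1.58 to 2.08) higher. Fscn1 was at 135 CPM in L-cDC and 53.0 CPM in M-cDC, 2.55-fold (95% interval 2.15 to 3.02) higher, and Ccr7, the receptor that guides mature dendritic cells to lymph nodes, was 2.40-fold (95% interval 1.72 to 3.34) higher. Of 5329 genes with enough counts, 453 differed by 1.5-fold or more, 238 higher in L-cDC and 215 lower. This number and the 43 of the cDC1-like cells came from unlike depths, with 1560177 and 3456569 UMIs in L-cDC. Counting error puts more genes past 1.5-fold at lower depth, which limits the contrast of the numbers. The cDC2-like class was named by a rule revised after a first naming had been seen. With cluster 6 in it, as first named, 747 genes differed by 1.5-fold or more. The balance turned towards lower genes when cells were classed by marker means (261 genes, 74 higher and 187 lower). It also did so when each library was clustered alone (704 genes, 296 higher and 408 lower). At a minimum of 5 CPM, 1112 genes differed, 508 higher and 604 lower. With each cell thinned to a fixed number of UMIs, 875 did, 357 higher and 518 lower, against 523 in cDC1-like cells. Inside both clusters of the class more genes were lower than higher too. Cluster 4 had 215 higher and 251 lower, and cluster 11 had 429 higher and 560 lower. At 5 CPM, after thinning and in cluster 11, the minimum of 50 UMIs again admits genes lower in L-cDC more readily, so part of these tilts is built in. More genes stayed higher at a minimum of 50 CPM (78 higher and 64 lower) and with cluster 6 added (380 higher and 367 lower).

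**Figure D2:**
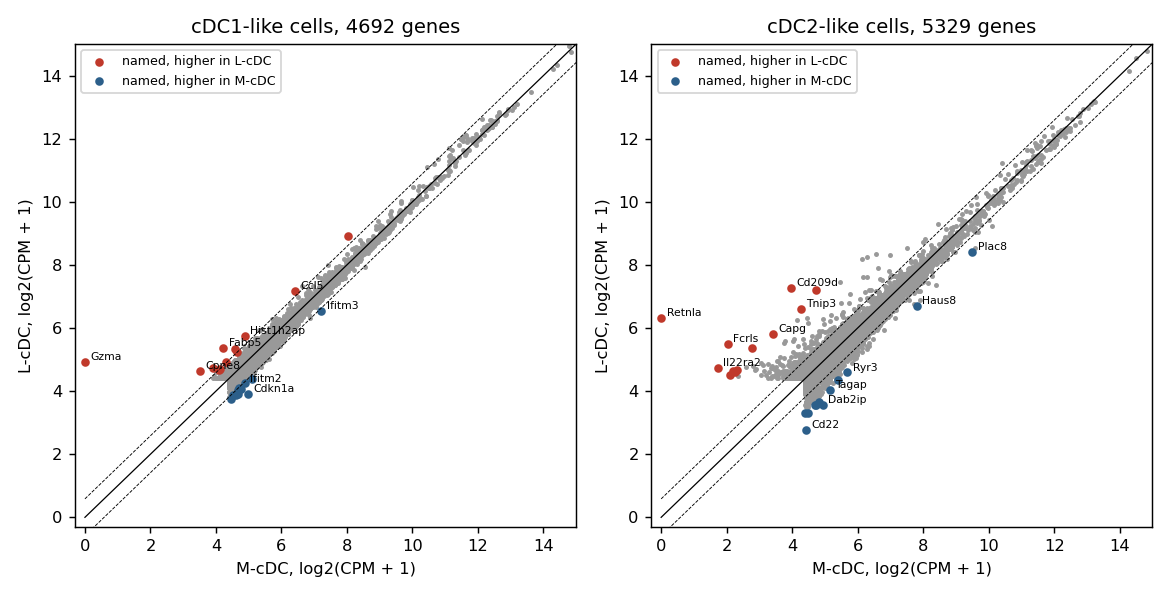
Expression of each gene with enough counts in L-cDC (vertical axis) against M-cDC (horizontal axis), both as log2 of CPM plus 1, in cDC1-like cells (left) and cDC2-like cells (right). Coloured points are named genes, some with labels, and dashed lines mark 1.5-fold; 43 genes lie on or past the lines on the left and 453 on the right.

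Several surface receptors were among the genes with the highest ratios in the cDC2-like cells of L-cDC. Cd209d, a C-type lectin of the DC-SIGN family and a top gene of cluster 8, was at 154 CPM in L-cDC and 14.5 CPM in M-cDC, 10.6-fold (95% interval 8.40 to 13.4) higher. Fcrls was 14.2-fold (95% interval 8.73 to 23.8) higher, although 15 of its 23 M-cDC UMIs came from 1 cell. Also higher were Mrc1, the mannose receptor, 6.92-fold (95% interval 4.62 to 10.5), Cd36, a scavenger receptor, 6.69-fold, and Capg, an actin-capping protein, 5.72-fold (95% interval 4.13 to 7.95). Ptgir, the prostacyclin receptor, was 6.19-fold higher, Dok2 6.08-fold and Tnip3 5.29-fold. Of 157 cDC2-like cells of L-cDC, only 36 carried a UMI of Cd209d, 20 of Fcrls, 15 of Mrc1 and 14 of Cd36. For Capg, Ptgir, Dok2 and Tnip3 the numbers were 28, 23, 12 and 34. These ratios thus rest on a minority of the class. Some of the highest ratios rested on single cells. All 123 UMIs of Retnla (at least 194-fold against a floor of 3 counts, exact lower 95% limit 155-fold) came from 1 cell, and 1 cell gave all of the L-cDC UMIs of Il22ra2, 59.5% of those of Fn1 (fibronectin) and 40.6% of those of the chemokine gene Cxcl9 (147 and 25.8 CPM). On the M-cDC side 1 cell gave 94.1%, 57.7% and 26.3% of the UMIs of these 3 genes. Lower in L-cDC were Plac8, at 337 and 721 CPM, Haus8 (104 and 222 CPM), Cd22, an inhibitory receptor of B cells (5.77 and 20.5 CPM), and Mcm5, a subunit of the replicative helicase (2.24-fold lower). The interferon-induced Isg20 and Phf11a were 2.27-fold and 2.35-fold lower, Cd300lf 2.17-fold, Ryr3 2.19-fold, Tagap 2.24-fold, Dab2ip 2.71-fold, Hist1h2ac 2.37-fold and Carmil1 2.34-fold. The direction of several of these genes turned under at least 1 alternative. The lowest log2 ratios among the alternatives were -0.99 for Cd36, -0.89 for Capg, -0.082 for Ptgir, -2.23 for Tnip3 and -2.24 for Cxcl9, and the highest were 0.67 for Plac8, 1.42 for Mcm5, 0.12 for Isg20 and 0.023 for Hist1h2ac. Mrc1, Fcrls, Dok2, Ptgir and Il22ra2 had 0 UMIs in L-cDC under at least 1 alternative, where their direction was not supported.

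Of the 22 measured cDC2 markers, 17 lay inside 1.5-fold between the origins, 4 were higher in L-cDC (Cd209d, Mgl2, Cd4 and Irf4) and 1, Dtx1, was lower (11.5 and 20.9 CPM). Sirpa was at 254 CPM in L-cDC and 236 CPM in M-cDC and Flt3 at 171 and 152 CPM. Clec4a4, the receptor DCIR2, was at 32.7 CPM in L-cDC and 39.2 CPM in M-cDC and Zbtb46 at 55.1 and 59.0 CPM. Cd4 was 1.54-fold (95% interval 1.247 to 1.90) higher in L-cDC, Irf4, a transcription factor cDC2 rely on, 1.51-fold (95% interval 1.16 to 1.94) higher, and Irf8 1.53-fold (95% interval 1.09 to 2.10) higher. Irf8 turned lower in L-cDC with at least 200 (-0.94) or 1000 (-1.08) genes per cell, with doublet-like cells kept (-0.53) and at Leiden resolution 2.0 (-1.08), and Cd4 when cells were classed by marker means (-0.21), all as log2 ratios. A UMI of Il7r was seen in 33 of 157 L-cDC cells (21.0%) and 84 of 970 M-cDC cells (8.66%), with medians of 9157 and 7253 UMIs per cell. In cDC1-like cells, where little Il7r is made, a UMI of Il7r was seen in 2.75% of L-cDC and 1.78% of M-cDC cells at medians of 15843 and 13934 UMIs.

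Of the gene groups fixed before the data were examined, markers of mature Ccr7+ dendritic cells stood highest in the cDC2-like cells of L-cDC, with a median log2 ratio of 1.03 (percentile 100) and 8 of 12 members past 1.5-fold. They included Serpinb6b (3.09-fold, 95% interval 2.28 to 4.18), Apol7c (195 and 70.3 CPM) and the chemokine gene Ccl22 (4.51-fold, with 42.9% of its L-cDC UMIs from 1 cell). The pDC markers had a median of 0.78 (percentile 100), with 5 of 7 past 1.5-fold: besides Tcf4, Lag3, an inhibitory receptor, was 2.22-fold (95% interval 1.64 to 2.98) higher, Smim5 1.90-fold, the gut-homing receptor Ccr9 1.72-fold (with 38.3% of its L-cDC UMIs from 1 cell) and Runx2, named after its values were seen, 1.54-fold, while 1, Lair1, was lower by that size (32.7 and 49.5 CPM). The lymphoid program, a list of genes of early lymphocyte development that shares Tcf4, Ly6d and Dntt with the pDC list, had a median of 0.36 (percentile 99.3), with 2 of 7 past 1.5-fold, Il7r and Tcf4, and Sox4 at 60.2 and 40.7 CPM. Of the 2 past 1.5-fold, Il7r is tied to the sort and Tcf4 is also a pDC marker. The mature class of both origins carried Il7r too, and mature markers were higher in these cDC2-like cells. Whether the rise of Il7r went with that of the mature markers was not tested. The median of all 5329 genes was -0.057. These 3 groups kept their sign under every alternative in which they were measured, which left out a minimum of 50 CPM for the pDC markers and the lymphoid program and at least 1000 genes per cell for the lymphoid program, with medians of 0.20 to 1.95, 0.42 to 1.69 and 0.16 to 1.04, and the log2 ratio of Il7r lay between 0.51 and 2.80.

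Monocyte-related and cholesterol genes were also higher as groups in the cDC2-like cells of L-cDC, though not in every member. Classical monocyte markers had a median of 0.83 (percentile 100), with 4 of 6 members higher by 1.5-fold and 1, Ms4a4c, lower (144 and 228 CPM). They included Ccr2, the receptor that brings monocytes out of bone marrow, at 325 CPM in L-cDC and 92.5 CPM in M-cDC, 3.51-fold (95% interval 3.13 to 3.95) higher, Csf1r, the receptor for macrophage growth factor, 1.79-fold higher, and Lyz2, lysozyme, 1.75-fold higher. ESAM-low cDC2 genes, which share Ms4a4c, stood at 0.44 (percentile 100), with 6 of 13 past 1.5-fold, among them Mgl2 (4.18-fold) and Cx3cr1 (1.997-fold), and 1 lower. Myeloid program genes stood at 0.43 (percentile 100), with 6 of 15 past 1.5-fold and 1, Cebpd, lower (36.5 and 55.1 CPM). Lipid and cholesterol genes stood at 0.42 (percentile 100), with 5 of 16 past 1.5-fold, among them Abcg1, a cholesterol exporter, 1.92-fold higher. cDC1 markers had a median of 0.61 (percentile 100), cDC2 markers 0.10 (percentile 99.8), cDC transcription factors 0.14 (percentile 99.97), migration genes 0.14 (percentile 99.6) and oxidative phosphorylation genes 0.039 (percentile 99.9). S phase genes were lower in L-cDC, with a median of -0.79 (percentile 0) and 6 of 8 members past 1.5-fold, among them Mcm4 (14.1 and 28.2 CPM), Mcm6 (21.2 and 36.9 CPM) and Mcm7 (14.7 and 26.04 CPM). Pattern recognition genes (-0.25, percentile 1.84) and immediate early and stress genes (-0.21, percentile 1.9) were lower by their medians. Of their members, 0 of 12 and 2 of 26 were lower by 1.5-fold and 1 and 1 higher, and Egr1 was at 73.1 and 107 CPM. MHC class II genes (-0.044) and interferon-stimulated genes (-0.090) lay inside the random range. Every group named in this paragraph as outside the random range, other than pattern recognition and immediate early genes, changed sign under at least 1 alternative, and counting error alone put 1.63% of unchanged genes past 1.5-fold in simulated libraries.

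Cluster 11 gave 63 of the 157 cDC2-like cells of L-cDC and 212 of the 970 of M-cDC, so the comparison was also made inside each cluster. In cluster 4, pDC markers (0.66, percentile 100), lymphoid program genes (0.70, percentile 100) and mature markers (0.52, percentile 100) were higher in L-cDC, while myeloid program genes (-0.039) and cDC1 markers (-0.14) lay inside the random range. In that cluster Il7r was 2.05-fold (95% interval 1.23 to 3.30) higher, Tcf4 1.62-fold, Runx2 2.05-fold, Cd4 1.77-fold and Sox4, a transcription factor of lymphoid progenitors, 2.01-fold (95% interval 1.56 to 2.57). In cluster 11, pDC markers (0.74, percentile 99.8) and mature markers (0.73, percentile 100) were higher, while the lymphoid program (0.16, percentile 77.2) was inside the random range although Il7r was 2.35-fold (95% interval 1.36 to 4.05) and Tcf4 1.80-fold higher. Ccr2 (1.99-fold), Mgl2 (2.35-fold), Cd209d (6.67-fold) and Mrc1 (3.995-fold) were higher within cluster 11 as well. S phase genes were lower in both clusters, at -0.44 and -0.99. Oxidative phosphorylation genes were 0.17 in cluster 4 and -0.060 in cluster 11. Interferon-stimulated genes (-0.18, percentile 0.67) and inflammatory genes of the NF-kB pathway (-0.18, percentile 1.38) were lower in cluster 4 of L-cDC by their medians only, which lay well inside 1.5-fold. Immediate early genes there stood at -0.19 (percentile 0.12) and ESAM-high cDC2 genes at 0.26 (percentile 99.3). In cluster 11 migration genes were at 0.27 (percentile 99.7), cDC1 markers at 0.35 (percentile 99.5) and cholesterol genes at 0.42 (percentile 99.98). Cholesterol genes in cluster 4 (0.12, percentile 91), ESAM-low genes in cluster 4 (0.030) and cluster 11 (0.058), and monocyte markers (0.17) and myeloid program genes (0.17) in cluster 11 were inside the random range, so of these rises over the class only that of cholesterol genes, in cluster 11, was found inside a cluster.

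**Figure D3:**
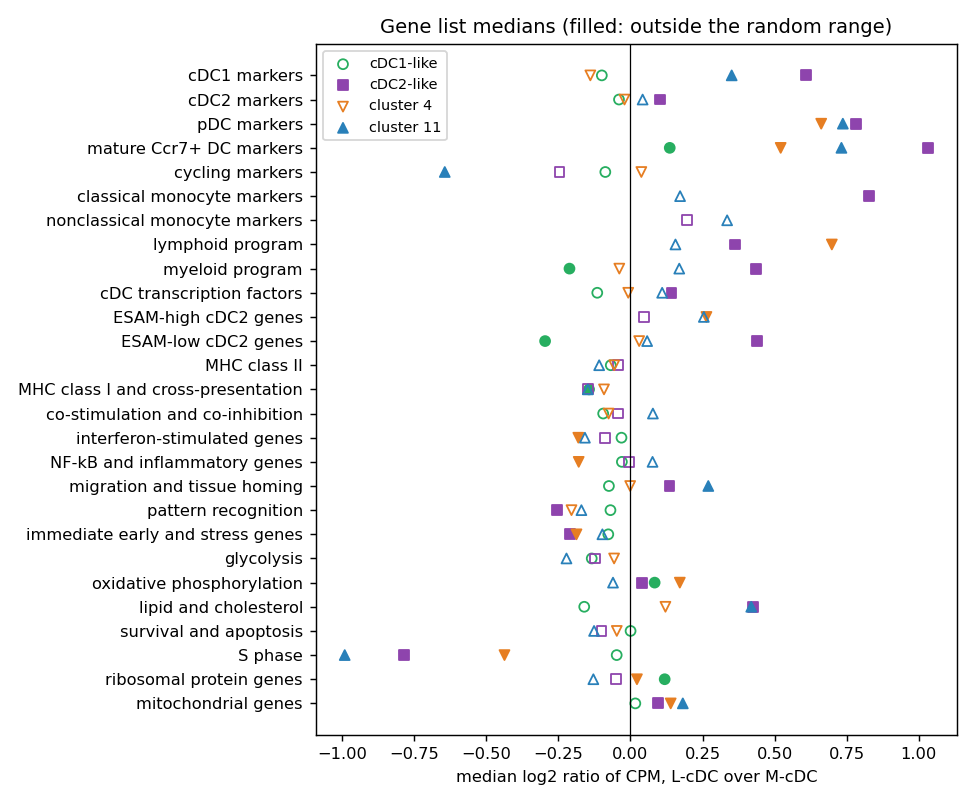
Median log2 ratio of L-cDC over M-cDC (horizontal axis) of each gene group (vertical axis) in cDC1-like cells, cDC2-like cells and the separate clusters 4 and 11. Filled points lie outside the central 95% of matched random gene lists; pDC and mature markers lie to the right of 0 in cDC2-like cells (0.78 and 1.03) and in both of its clusters.

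Whole profiles showed how far origin and cell type separated these cells. Across 6339 genes at 20 CPM or more in any of the profiles, which are not independent replicates, the Pearson correlation of log2 expression between L-cDC and M-cDC was 0.991 for cDC1-like cells, 0.969 for cDC2-like cells, 0.962 for cluster 8 and 0.995 for mature cells. Between cDC1-like and cDC2-like cells it was 0.822 within L-cDC and 0.840 within M-cDC. Over the same genes with 1 CPM added and without a minimum of UMIs, 38 genes differed by 2-fold by origin in cDC1-like cells and 197 in cDC2-like cells, against 1203 genes between the cell types within L-cDC and 1058 within M-cDC. Among the genes with enough counts in the comparisons by origin, 4 and 114 differed by 2-fold. The cDC2-like sums held fewer UMIs than the cDC1-like sums, which limits these contrasts too.

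The differences by origin were weakly shared between cDC1-like and cDC2-like cells. Across 4394 genes the log2 ratios of cDC1-like and cDC2-like cells correlated at 0.176 (Pearson) and 0.192 (Spearman). Any difference between the libraries as a whole enters both ratios. Fscn1 and Gadd45b were among the genes higher, and Ifitm3, Fam53a, Hist1h1b and Bag5 lower, in L-cDC by 1.5-fold or more in both classes. In cDC1-like cells the directions of Fscn1, Gadd45b, Hist1h1b, Ccl5 and Cdkn1a each turned under an alternative. Ccl5 was higher in cDC1-like and lower in cDC2-like cells of L-cDC (528 and 818 CPM), and Cdkn1a was lower in cDC1-like and higher in cDC2-like cells (42.3 and 17.0 CPM). Classing every cell by marker means gave a coefficient of 0.858.

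Cluster 8, the cells with both cDC2 and pDC markers, differed by origin in several lymphoid and pDC genes. In L-cDC these cells carried more Il7r (227 and 58.6 CPM, 3.89-fold, 95% interval 3.10 to 4.92), more Cd8a (303 and 77.2 CPM, 3.92-fold, 95% interval 3.22 to 4.81), more Irf8 (93.9 and 22.6 CPM, 4.15-fold) and more Tcf7, a transcription factor of T and innate lymphocytes (3.45-fold). The pDC lectin Siglech was at 141 and 41.9 CPM, 3.35-fold (95% interval 2.56 to 4.46) higher, Lag3 at 203 and 106 CPM and Cd4 at 53.0 and 18.0 CPM. A UMI of Il7r was found in 64.9% of L-cDC and 23.2% of M-cDC cells of the cluster, of Cd8a in 62.9% and 22.5%, and of Siglech in 49.0% and 28.3%, at medians of 12454.5 and 10547.5 UMIs. In cDC1-like cells, Il7r was found in 2.75% and Siglech in 1.38% of L-cDC cells, and in cDC2-like cells, Cd8a was found in 0.637%. Ly6d, a surface protein of lymphoid and pDC progenitors, had 481 UMIs in L-cDC and 0 in M-cDC, at least 93.9-fold higher against a floor of 3 counts (exact lower 95% limit 76.0-fold), but only 16 of 194 cells carried one.

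By group, cluster 8 of L-cDC had higher mature markers (0.65, percentile 100; Fscn1 2.19-fold), ESAM-high cDC2 genes (0.64, percentile 99.98; Adam23 2.46-fold), pDC markers (0.39, percentile 99.99), cDC1 markers (0.37, percentile 99.97) and lymphoid program genes (0.35, percentile 99.7). Interferon-stimulated genes were lower as a group, at -0.47 (percentile 0), with 8 of 19 members lower by 1.5-fold, such as Samd9l (29.99 and 72.5 CPM), and 3 higher, such as Ly6a (70.9 and 16.6 CPM). Ifitm3, named after its values were seen, was at 311 CPM in L-cDC and 1057 CPM in M-cDC, 3.40-fold (95% interval 3.12 to 3.71) lower. Other genes lower in L-cDC were the lectin Clec12a (42.1 and 92.5 CPM), Ms4a4c (98.2 and 239.5 CPM), Ccr2 (159.7 and 262 CPM), Nlrp3 (8.18 and 23.3 CPM) and Batf3, a transcription factor of cDC1 (38.6 and 74.5 CPM). Of 5233 genes, 610 passed 1.5-fold, 305 higher and 305 lower in L-cDC.

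**Figure D4:**
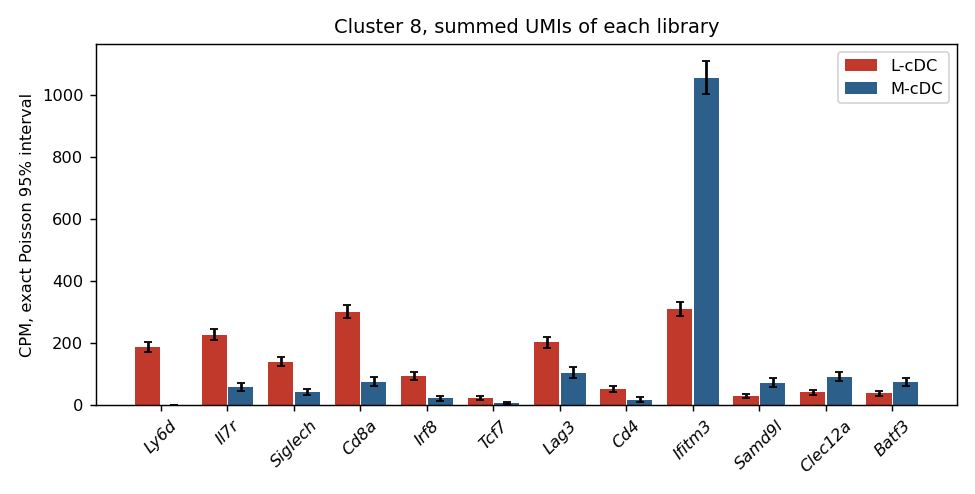
Expression (CPM, vertical axis) of 12 genes in cluster 8 for L-cDC (red) and M-cDC (blue), with exact Poisson 95% intervals as error bars. Il7r, Siglech, Cd8a, Irf8, Tcf7, Lag3 and Cd4 are higher in L-cDC, Ly6d has 481 UMIs in L-cDC and 0 in M-cDC, and Ifitm3, Samd9l, Clec12a and Batf3 are lower.

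The mature class, from which the unnamed clusters 7, 9, 12 and 15 were left out, was alike in both origins when pooled, and 27 of 4315 genes passed 1.5-fold. Inside its clusters 1 and 2, 26 of 4300 and 22 of 4355 genes did. Inside its clusters 5 and 10, which were summed from fewer UMIs, 175 of 3256 and 338 of 4298 genes did. With cluster 7 in the mature class, as first named, 79 of 4364 genes did, and the class held 59.6% of L-cDC and 49.9% of M-cDC cells. Il7r was at 260.1 CPM in L-cDC and 235 CPM in M-cDC, so cells sorted as tdTomato-negative carried Il7r transcripts too. Bcl2l14 (194 and 292 CPM), the interleukin 12 subunit gene Il12b (23.9 and 36.6 CPM) and Irf8 (188 and 234 CPM) were lower in L-cDC, and Hist1h2ap (1.90-fold) and Cybb, a subunit of the phagocyte oxidase (1.54-fold), were higher. The class pooled clusters 1, 2, 5 and 10, of which cluster 1 gave 1101 of 1995 L-cDC cells and 1240 of 2794 M-cDC cells. Oxidative phosphorylation genes stood at 0.14 (percentile 100) over the class and were higher in L-cDC inside each of these clusters, at 0.22, 0.11, 0.087 and 0.18. Ribosomal protein genes (0.067, percentile 100) and mitochondrial genes (0.16, percentile 99.9), lists not fixed beforehand, were outside the random range too. MHC class II genes (0.10, percentile 99.5) and interferon-stimulated genes (0.051, percentile 99.5) were higher over the class. Inside the clusters their medians were below 0, at -0.12, -0.13, -0.12 and -0.14 and at -0.047, -0.093, -0.046 and -0.081, so their class medians described none of the clusters. The medians of all considered genes there were below 0 too, at -0.034, -0.049, -0.022 and -0.037. A median below 0 therefore does not by itself mark a fall of the list. The lymphoid and myeloid programs, cDC1 markers and lipid genes were outside the random range over the class as well, but each changed sign in at least 1 of the clusters. Cycling cells (75 in L-cDC and 277 in M-cDC) also differed: in L-cDC all 17 measured mature markers were higher by 1.5-fold (median 2.09), as were pDC (1.12), lymphoid (1.10) and cDC2 (0.84) groups by their medians, while cDC1 markers (-0.24) and S phase genes (-0.36) were lower. The class pooled cluster 13, second in score for cDC2, with clusters 16 and 18, second for cDC1. They held 42, 20 and 13 L-cDC cells and 138, 91 and 48 M-cDC cells, and were not compared one by one. In those cycling cells Il7r was 3.75-fold (95% interval 2.52 to 5.58) higher, Tcf4 2.80-fold and the cytokine signalling inhibitor Socs2 15.3-fold. They carried 40.9 unscaled UMIs of 12 mature markers per cell in L-cDC and 9.17 in M-cDC, and mature L-cDC cells carried 161. RNA from mature cells and doublets with them were not tested for the cycling cells.

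Some genes differed between the libraries over all kept cells. The ribosomal protein genes Rpl35 (1626 and 1138 CPM over all kept cells), Rps27 (2994 and 2087 CPM) and Rpl38 (1991 and 1428 CPM), chosen after their values were seen, were higher in L-cDC. Gt(ROSA)26Sor was lower in L-cDC, at 16.7 and 24.99 CPM over all kept cells, 16.8 and 26.6 CPM in cluster 8 and 24.4 and 29.7 CPM in cDC2-like cells. Neither tdTomato nor Cre was among the 31053 genes of the deposited tables. A UMI of Igkc, the antibody light chain of B cells, appeared in 21.1% of cDC1-like, 15.9% of cDC2-like and 13.3% of mature L-cDC cells, against 1.10%, 0.515% and 0.215% in M-cDC. In NK cell-like cells of L-cDC it was 22.6%.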

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

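Of the tests reported in this part, the one on the weights of clusters 4 and 11 was chosen only after the result was seen, as were the one on RNA from lymphocytes over all members, which replaced a sum over the members higher in L-cDC, the argument from mixtures about cluster 7, and the scaling of L-cDC to the depth of M-cDC, by class and by library, in the tests on free RNA and on doublets with mature cells. Without the scaling their values, in the order given below, were 9.26% (0.0236 to 21.8), 26.04% (16.2 to 38.0) and 62.7% (54.1 to 71.2), and the last would have counted against doublets. Several small groups of cells outside the comparisons made up a larger share of the L-cDC library. NK cell-like cells, led by Gzma, Nkg7 and Ncr1, made up 3.70% of kept L-cDC cells and 0.0179% of M-cDC cells. B cell-like cells, led by Iglc2, Igkc and Cd79a, made up 1.32% of L-cDC cells, while 0 of 5600 M-cDC cells were of this kind, with an upper Clopper-Pearson 95% bound of 0.0659%. Red pulp macrophage-like cells, led by Apoe, C1qb and C1qa, made up 1.32% of L-cDC and 0.446% of M-cDC cells. Cluster 20, led by Gzmc, Ctsw and Xcl1, was unnamed because no marker of its highest-scoring list was among its top 10 genes. It held 1.29% of L-cDC cells and 0 M-cDC cells. All had passed the CD11c enrichment and the tdTomato sort. Between the cDC1-like and cDC2-like classes, 2 genes at 1.5-fold in both went in opposite directions, Ccl5 and Cdkn1a, and 7 went in the same direction, a difference that was not tested.

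The first pattern weighed was that pDC marker and lymphoid program genes were higher in the cDC2-like cells of L-cDC, whose library also held NK and B cell-like cells. RNA set free by these lymphocytes would raise the genes in cDC1-like cells too, but the excess per cell of all measured members of both lists there, scaled by class (2.88 against 3.04 UMIs) was -12.8% (-45.6 to 9.91) of that in cDC2-like cells (5.59 against 4.36 UMIs) and 1.05% (-11.6 to 14.2) of it when scaled by library, which argues against it. A different weight of clusters 4 and 11 was argued against by cluster 4 alone, where the lower of the list medians was 0.66, above its random range. As a biological explanation, cells of cluster 4 in L-cDC could lie nearer to cluster 8, but across 5569 genes their shift correlated with the cluster 8 profile at 0.0953 (0.0692 to 0.121), which spans the bound set for its absence, so this stays open. That interval takes genes as independent, which they are not, so it may be too narrow. A difference between the preparation of the libraries was not tested, since each origin had 1. RNA from mature cells, which carried Il7r too, and doublets with them were not tested for these genes.

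The second pattern was cluster 7, with 355 cells in L-cDC (9.003%) and 1 in M-cDC. A shift of the whole library was predicted to leave it close to a mature cluster of M-cDC. From the nearest, cluster 10, 896 of 5004 genes differed by 2-fold, while at most 54 did between the libraries inside a mature cluster. Clustering on these same data had already set cluster 7 apart, so a number above that inside a cluster was built in. The comparison therefore could not decide. For doublets of a pair of L-cDC cell kinds, 8 genes stood 2-fold or more above every other L-cDC cluster of at least 20 cells, between the bounds set beforehand of at most 1 gene for doublets and at least 10 against them, so the test did not decide. After the 8 had been seen, a bound of more than 1 gene was tried because a mixture cannot exceed its higher parent in any gene, but it was dropped, since parents could be a part of a cluster. No biological explanation was tested, and a cell kind that the sort or the preparation let into 1 library may account for the cluster.

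The third pattern was that markers of mature Ccr7+ dendritic cells were higher in the cDC2-like cells of L-cDC (8.26 against 5.31 UMIs per cell, scaled by class). For RNA set free by mature cells, the excess in cDC1-like cells (8.04 against 7.81 UMIs) was 7.68% (-7.08 to 24.98) of that in cDC2-like cells scaled by class and 15.7% (6.02 to 27.8) scaled by library, whose interval crosses the bound of 25% set for its absence, so the data could not decide. NK cell-like and B cell-like cells of L-cDC carried 11.2 and 39.0 unscaled UMIs of these markers per cell. For a few doublets with mature cells, 54.5% (41.9 to 67.2) of the excess scaled by class and 60.9% (51.5 to 70.3) scaled by library was left without the 5% of cells with the most marker UMIs, and the first interval crosses the bound of 50% set against doublets, so this was not decided either. No biological explanation was tested here, and further maturation of these cells in L-cDC, free RNA and doublets stay open.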

How the results depend on the processing

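Of the values in this part, those for each library's own Scrublet threshold, for other memberships of the classes (clusters 6 and 7 as first named, cluster 8, cycling clusters, clusters 3, 4 or 11 alone, and clusters 4 and 11 reweighted) and without the cell richest in each gene came from alternatives chosen after seeing the data; the others were chosen before. No paired analysis was possible because each group had 1 library. Over 23 alternatives, the 15 cDC2-like lists outside the random range gave 333 medians where enough members were measured, of which 49 in 10 lists changed sign; lists that kept their sign were pDC markers (0.42 to 1.69), mature Ccr7+ DC markers (0.20 to 1.95), lymphoid program (0.16 to 1.04), pattern recognition (-0.54 to -0.041) and immediate early and stress genes (-0.53 to -0.10). Over 19 alternatives, the 5 cDC1-like lists gave 94 medians and 2 changed sign. Of 683 ratios of 36 named cDC1-like genes, 7 changed sign, and of 814 ratios of 36 named cDC2-like genes, 28 in 12 genes did; 40 and 50 of these ratios had 0 UMIs in a library and are bounds from the floor of 3 counts, which need not fix a direction. A smaller expression minimum admits more genes by construction, and a larger one fewer; thinning adds counting error by construction. For the other values below the cause was not tested, and shares are L-cDC minus M-cDC. No cDC1-like or cDC2-like cluster was led by cycling or Ccr7-type genes, so leaving those out changed nothing. The depth of 1560177 UMIs in the cDC2-like cells of L-cDC limits ratios of genes near 20 CPM.

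With at least 200 genes per cell, the share difference was -7.15 points for cDC1-like and -12.0 points for cDC2-like cells, 7 cDC2-like lists were outside the random range and the correlation was 0.135. cDC1 markers, cDC2 markers, myeloid program, cDC transcription factors, ESAM-low cDC2 genes and migration and tissue homing had cDC2-like medians of -0.17, -0.11, -0.18, -0.079, -0.19 and -0.077. Log2 ratios reversed for Cxcl9, Tnip3 and Irf8 in cDC2-like cells, to -1.06, -1.64 and -0.94. With at least 1000 genes per cell, the share difference was -8.05 points for cDC1-like and -12.0 points for cDC2-like cells, 5 cDC2-like lists were outside the random range and the correlation was 0.147. The cDC2-like medians of cDC1 markers, cDC2 markers, classical monocyte markers, myeloid program, cDC transcription factors and ESAM-low cDC2 genes were -0.17, -0.12, -0.025, -0.025, -0.025 and -0.082. Reversed log2 ratios were -0.99, -2.24, -0.89, -0.082, -1.08 and 0.0058 for Cd36, Cxcl9, Capg, Ptgir, Irf8 and Hist1h2ac in cDC2-like cells. At no more than 5% mitochondrial UMIs, 3 cDC1-like lists were outside the random range. Il22ra2 in cDC2-like cells had a log2 ratio of at most -0.13. With Scrublet-marked cells kept, the share difference was -8.79 points for cDC1-like and -11.2 points for cDC2-like cells, 9 cDC1-like lists were outside the random range and the correlation was 0.136. cDC2-like medians reversed for cDC1 markers, cDC2 markers, myeloid program, cDC transcription factors, ESAM-low cDC2 genes and lipid and cholesterol, to -0.17, -0.22, -0.22, -0.00051, -0.43 and -0.046. The log2 ratios of Cd36, Cxcl9 and Irf8 in cDC2-like cells were -0.11, -0.92 and -0.53. The cDC1-like median of mature Ccr7+ DC markers was -0.46. The log2 ratios of Fabp5, Fscn1, Gadd45b and Ccl5 in cDC1-like cells were -0.36, -1.12, -0.49 and -0.31. At each library's own Scrublet threshold, the share difference was -10.7 points for cDC2-like cells. cDC2-like medians reversed for cDC1 markers, cDC2 markers and myeloid program, to -0.12, -0.051 and -0.063. The log2 ratios of Cxcl9 and Tnip3 in cDC2-like cells were -0.83 and -1.23. At Leiden resolution 0.5, the share difference was -14.2 points for cDC2-like cells. At Leiden resolution 2.0, the share difference was -12.7 points for cDC2-like cells and 8 cDC2-like lists were outside the random range. Reversed cDC2-like medians were -0.15, -0.076, -0.058, -0.045, -0.034 and -0.00093 for cDC1 markers, cDC2 markers, myeloid program, cDC transcription factors, migration and tissue homing and lipid and cholesterol. Cd36, Isg20 and Irf8 in cDC2-like cells had log2 ratios of -0.45, 0.12 and -1.08. With each library clustered alone, the share difference was -4.03 points for cDC1-like and -9.03 points for cDC2-like cells, 113 cDC1-like and 704 cDC2-like genes passed 1.5-fold, 10 cDC1-like lists were outside the random range and the correlation was 0.394. cDC2-like medians reversed for cDC1 markers, cDC2 markers, myeloid program, cDC transcription factors, migration and tissue homing, lipid and cholesterol and S phase, to -0.29, -0.33, -0.35, -0.046, -0.35, -0.047 and 1.30. The log2 ratios of Cxcl9, Plac8, Tnip3 and Mcm5 in cDC2-like cells were -2.23, 0.45, -2.23 and 1.42. The log2 ratios of Orc6 and Hist1h1b in cDC1-like cells were 0.58 and 0.14. Classing each cell by its marker means, the share difference was -8.70 points for cDC1-like and 8.70 points for cDC2-like cells, 114 cDC1-like and 261 cDC2-like genes passed 1.5-fold, 12 cDC1-like lists were outside the random range and the correlation was 0.858. cDC1 markers, cDC2 markers, classical monocyte markers, cDC transcription factors, ESAM-low cDC2 genes and migration and tissue homing had cDC2-like medians of -0.21, -0.00093, -0.32, -0.031, -0.33 and -0.024. Log2 ratios reversed for Cxcl9 and Cd4 in cDC2-like cells, to -0.0072 and -0.21. The cDC1-like median of MHC class I and cross-presentation was 0.0078. The log2 ratio of Cdkn1a in cDC1-like cells was 0.047. Among cDC1-like plus cDC2-like cells, the share difference was 15.2 points for cDC1-like and -15.2 points for cDC2-like cells. Scaled without mitochondrial, ribosomal protein and immunoglobulin genes, 82 cDC1-like genes passed 1.5-fold. At a minimum of 5 CPM, 405 cDC1-like and 1112 cDC2-like genes passed 1.5-fold and the correlation was 0.116. At a minimum of 50 CPM, 11 cDC1-like and 142 cDC2-like genes passed 1.5-fold, 8 cDC2-like lists were outside the random range and the correlation was 0.344. Migration and tissue homing had cDC2-like a median of -0.00068. With each cell thinned to 3000 UMIs, 523 cDC1-like and 875 cDC2-like genes passed 1.5-fold, 1 cDC1-like list was outside the random range and the correlation was 0.0605. cDC2-like median reversed for cDC1 markers, to -0.24. Counting cluster 8 as cDC2-like, the share difference was -10.9 points for cDC2-like cells and the correlation was 0.140. The log2 ratio of Plac8 in cDC2-like cells was 0.67. With cluster 6 in the cDC2-like class, as first named, the share difference was -15.3 points for cDC2-like cells, 747 cDC2-like genes passed 1.5-fold and the correlation was 0.211. Reversed cDC2-like median was -0.042 for oxidative phosphorylation. Adding cycling clusters by marker means, the share difference was -9.13 points for cDC1-like and -14.7 points for cDC2-like cells, 9 cDC1-like lists were outside the random range and the correlation was 0.259. Hist1h2ac in cDC2-like cells had a log2 ratio of 0.023. For cluster 4 alone, 9 cDC2-like lists were outside the random range. cDC2-like medians reversed for cDC1 markers, cDC2 markers, myeloid program, cDC transcription factors and migration and tissue homing, to -0.14, -0.021, -0.039, -0.0075 and -0.00087. The log2 ratios of Cxcl9 and Tnip3 in cDC2-like cells were -1.15 and -0.98. For cluster 11 alone, 989 cDC2-like genes passed 1.5-fold and 7 cDC2-like lists were outside the random range. Reversed cDC2-like median was -0.060 for oxidative phosphorylation. Weighting clusters 4 and 11 of M-cDC as in L-cDC, the correlation was 0.213. With cluster 7 in the mature class, its share difference was 9.69 points against 0.703 without it, and 79 genes passed 1.5-fold against 27.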

Other observations

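No test is reported in this part, and the clusters and genes given were chosen after their values had been seen. Cluster 7 of L-cDC resembled mature dendritic cells in part. Beside the other mature L-cDC cells it carried more S100a4, a calcium-binding protein of motile cells (1889 against 52.6 CPM), more of the filament gene Vim (2773 against 339.9 CPM), and more of the chemokine genes Ccl17 (373 against 111 CPM), Ccl22 (1187 against 551 CPM) and Ccl5 (8074 against 5944 CPM). Fscn1 was at 2295 against 1772 CPM, Sirpa at 87.1 against 15.4 CPM and the transcription factor gene Relb at 738 against 952 CPM. It carried less Ccr7 (499.9 against 1341 CPM), less of the MHC class II gene H2-Ab1 (446 against 2247 CPM) and less Cd74 (4809 against 12146 CPM). The genes that set it apart from every other L-cDC cluster of at least 20 cells were Clu, Ltc4s, Mucl1, Mfge8, Nrp2, H2-M2, Sod3 and Dap. H2-M2, a class I-like gene, was at 2253 CPM with a UMI in 96.6% of its cells, Clu (clusterin) at 475 CPM in 55.5%, Nrp2 at 345 CPM in 69.3%, and Ltc4s, which makes leukotriene C4, at 241 CPM in 67.3%. Mucl1 came from 25 cells.

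Smaller clusters held other states in both libraries. Cluster 23, led by the interferon-induced genes Cxcl10, Ifit3 and Irf7, held 6 L-cDC and 24 M-cDC cells. Cluster 10, led by Ccl17, Il12b, Ccl22 and Cd40, held 3.60% of L-cDC and 2.52% of M-cDC cells. Cluster 9, led by Nid1, Lyz2 and Il1b among others, held 4.49% and 2.05%, and cluster 6, led by Ryr3, Mdk and Ccnd1 among others, 4.51% and 6.43%. Cluster 12, led by Gm26917, Zfc3h1 and Malat1 among others at a median of 1882 UMIs per cell, held 4.64% of L-cDC and 1.54% of M-cDC cells.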
